A study of Homo sapiens with 14 samples.

How the data were processed

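The series holds RNA sequencing of 2 human cell lines, HEC-1-B (an endometrial adenocarcinoma line) and HEK-293T (a line from embryonic kidney). The 14 libraries fall into 7 groups of 2: wild-type HEC-1-B, mE1, mE1_CBSmut, mE2, mE2_CBSmut and ac1rep (all HEC-1-B), and wild-type HEK-293T. Per the labels, mE1 and mE2 are insertions made by editing and ac1rep carries a repeat named ac1. The CBSmut groups are set apart by their titles alone, since their genotype field reads mE1 or mE2. The labels do not say whether the libraries of a group came from separate cultures or clones, so all p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, HEC-1-B was grown in MEM and HEK-293T in DMEM, RNA was extracted with TRIZOL, polyadenylated RNA was captured on magnetic beads, and libraries were built with a NEBNext Ultra II kit. Whether reads were assigned by strand is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart in these values.

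The authors deposited 1 table of FPKM values per library (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with an interval and a status for each transcript. The submitters' processing notes name HISAT2 2.0.4, Cufflinks 2.1.1 and the genome build GRCh38/hg38, with no settings. Each table holds 57690 transcript entries with RefSeq identifiers, gene symbols and coordinates, per the file headers. Transcripts of a symbol were summed. Of 26601 symbols, 371 with different entries between files and 327 with an entry marked as low data or failed were set aside, some for both reasons, which left 25936. The tables of the ac1rep libraries differ from those of wild-type HEC-1-B in 403 entries. FPKM values do not give read totals, so sequencing depth is unknown. Interval widths of single-entry symbols give an estimated 1.56 M to 2.48 M fragments (M for mega) in 12 libraries. In ac1rep they give 0.967 M to 1.12 M. All are partial sums. Summed FPKM was 596 k to 688 k in those 12 libraries (k for kilo) and 384 k to 389 k in ac1rep. The small nucleolar RNA SNORD141A alone took 28.3% to 49.1% of summed FPKM in the 12 libraries. In the ac1rep tables no entry is marked as low data, and where the lower bound of the interval is above 0 (16534 and 17132 entries) each FPKM lies within 1% of its middle. Of such entries 60.4% to 66.9% do so in the other 12 libraries. Among the other 12 libraries, 13.6% to 38.4% of the FPKM values compared lie outside their own interval. The ac1rep tables were therefore made in a different way from the others, and every comparison with ac1rep carries that difference.

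Values were analysed as log2(FPKM + 0.5), and a fold change on this scale understates the change of genes with low FPKM. A gene was tested where FPKM reached 0.5 in at least 2 libraries, which left 15022 genes. FPKM values are not counts, so no count model was used. limma 3.58.1 in R 4.3.3 was fitted to all 14 libraries with 1 mean per group (7 residual degrees of freedom), with a trend of the prior variance on expression, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. A permutation of 2 libraries against 2 cannot give a p below 0.333, so the tests rest on the spread pooled over groups. The 10 comparisons are each edited group against wild-type HEC-1-B, each CBSmut group against its own insertion, ac1rep against HEK-293T, HEK-293T against HEC-1-B, and the difference of the CBSmut effects between mE1 and mE2. Comparisons that share the wild-type libraries, or the mE1 or mE2 libraries, share their chance values. Replicates were compared first, and at most 0.00317% of transcript entries above 0 were identical between the libraries of a group.

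A total of 28 gene lists were fixed, and camera in limma tested each list with at least 3 tested members against all other tested genes, with a preset correlation of 0.01 and adjustment over the lists of a comparison. An estimated correlation was the alternative. The lists are PCDHA, PCDHB and PCDHG genes, other protocadherins, genes neighbouring the PCDH clusters, CTCF and cohesin, DNA methylation, mitotic cell cycle, DNA replication, p53 targets, interferon response, unfolded protein response, integrated stress response, hypoxia, cholesterol synthesis, mesenchymal genes, epithelial markers, endometrial genes, HEK-293T markers, fibroblast, immune and endothelial markers, immediate early genes, replication histones, mitochondrial transcripts, ribosomal proteins, Wnt targets, and cell adhesion and extracellular matrix. Genes are named by a rule with 4 parts. These are every tested PCDHA gene with CTCF and RAD21, the 10 largest positive and 10 largest negative log2 differences among called genes, the 3 members with the smallest p in each list called by camera, and up to 10 called members of the PCDHB, PCDHG and neighbouring lists. The second part asks for a mean FPKM of at least 1 in 1 group and no overlap between the libraries of the groups, leaves out clone, small RNA and similar symbols, and takes 5 and 5 genes for HEK-293T against HEC-1-B, ac1rep against HEK-293T and each CBSmut group against wild type. Some genes that met the rule are not reported here. The grouping, the main test, the lists, the rule and a first set of other settings were chosen before the data were examined.

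Those settings were other pseudocounts (0.1 and 1), other filters, quantile normalization, median-ratio scaling, the highest transcript per gene in place of the sum, the replicate number as a block, a fit to only the groups compared, and leaving out each library in turn, in which case the lone library of a group is assumed to vary like those of the other groups. Settings chosen after seeing the data were the middle of each deposited interval in place of FPKM where its lower bound is above 0, removal of a loess trend (span 0.3) of each library on GC content and transcript length for the 14084 tested genes (93.8%) with both values, leaving out 333 genes with an entry on an alternate or unplaced sequence, fits without the ac1rep or mE1_CBSmut libraries, a fold change of at least 2 beside the adjusted p, and the block together with only the groups compared for mE1_CBSmut against wild type. Positions were summarised over 141 bins of 20 Mb holding at least 25 genes with a mean FPKM of at least 2 (10527 genes) and set against 1000 shuffles of gene positions. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The test was tried on simulated data made from the mE1 and wild-type libraries. It recovered 71% of genes changed 2-fold and 92% of genes changed 4-fold among 15022 genes, and called 7 of 14822 unchanged genes.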

Results

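RNA was sequenced from 14 libraries, 2 for each of 7 groups of cells, in a series whose title concerns CTCF and the choice between duplicated enhancers at the protocadherin alpha locus. HEC-1-B cells, an endometrial adenocarcinoma line, were either wild type or carried an insertion (mE1 or mE2), an insertion with a changed CBS (mE1_CBSmut or mE2_CBSmut, where CBS is the field's usual short form for a CTCF-binding site) or a repeat named ac1 (ac1rep). HEK-293T cells were wild type. The labels do not say where in the genome the insertions, the changed CBS or the repeat lie. Levels are FPKM, given as mean ± SD over the 2 libraries of a group (n = 2), and positions are on GRCh38. Differences are on the log2(FPKM + 0.5) scale, as the first group named minus the second, with the adjusted p of limma. The files hold no read totals, so depth is unknown. The intervals of symbols with a single transcript entry correspond to an estimated 0.967 M to 2.48 M fragments (M for mega), which is a part of each library. Between 11421 and 12327 genes reached 1 FPKM in the 12 libraries other than ac1rep, and 10515 to 10556 in the ac1rep libraries.

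The protocadherin alpha genes (PCDHA) lie in tandem on chromosome 5 and encode neuronal cell-surface cadherins, with first exons of their own spliced to shared last exons. Of the 15 genes listed, 4 reached the level for testing. PCDHA6 starts at 140827922, PCDHA12 at 140875302, PCDHAC1 at 140926717 and PCDHAC2 at 140966162, and all end at 141012344, so reads from the shared exons cannot be assigned to 1 gene with certainty and single-gene values depend on how they were divided. In wild-type HEC-1-B the levels were 2.66 ± 0.240 FPKM for PCDHA6, 4.02 ± 0.639 for PCDHA12, 1.64 ± 0.263 for PCDHAC1 and 2.73 ± 0.0509 for PCDHAC2. The sum over all PCDHA genes was 11.9 ± 0.681 FPKM in wild type, 9.22 ± 0.670 in mE1, 11.8 ± 0.241 in mE1_CBSmut, 11.4 ± 0.608 in mE2, 11.3 ± 0.0681 in mE2_CBSmut and 4.76 ± 0.288 in ac1rep. PCDHA12 made up 33.8% ± 3.45 of that sum in wild type and 53.01% ± 0.466 in mE1, and PCDHA6 made up 22.4% ± 0.735 in wild type and 33.8% ± 2.97 in mE2, shares that were not tested. In HEK-293T, PCDHA6, PCDHA12 and PCDHAC1 were listed at 0 in both libraries and PCDHAC2 at 0 and 0.0138 FPKM.

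**Figure D1:**
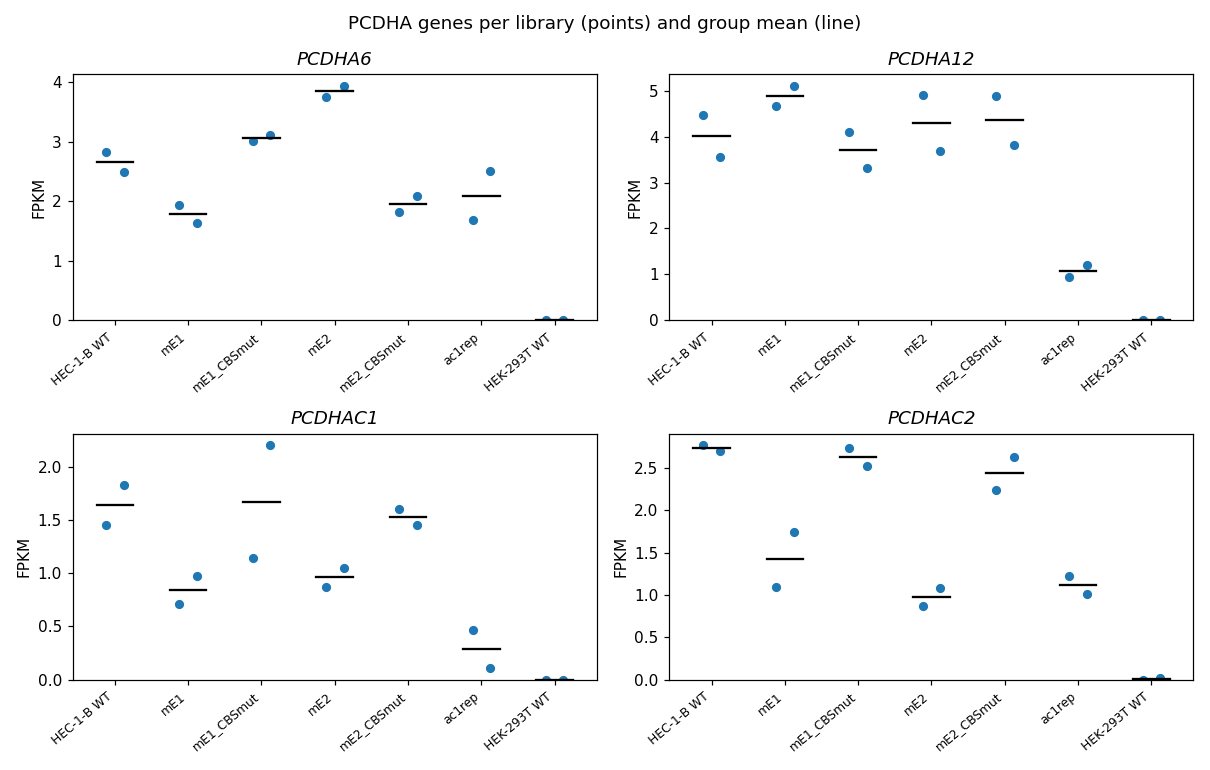
FPKM (vertical axis, linear from 0) of PCDHA6, PCDHA12, PCDHAC1 and PCDHAC2, 1 panel each, in the 7 groups (horizontal axis), with a point for each of the 2 libraries and a line at their mean. PCDHAC2 was at 1.42 FPKM in mE1 and 0.976 in mE2, below the 2.73 of wild type, and was at 2.63 and 2.44 in the CBSmut groups.

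The mE1 insertion was set against wild-type HEC-1-B to measure its effect on PCDHA genes and on the rest of the transcriptome. PCDHAC2 fell from 2.73 ± 0.0509 to 1.42 ± 0.461 FPKM (log2 difference −0.77, adjusted p = 0.00469). PCDHA6 fell from 2.66 ± 0.240 to 1.79 ± 0.216 (log2 −0.47, adjusted p = 0.0385). PCDHA12 was at 4.89 ± 0.312 FPKM (log2 0.26, adjusted p = 0.287) and PCDHAC1 at 0.842 ± 0.185 (log2 −0.68, adjusted p = 0.0633), and neither passed the test. Of the 4 genes, 2 fell over all genes and 3 adjusted over the list alone, and camera did not call the list (adjusted p = 0.674). The PCDHA6 call was lost without any 1 of the 4 libraries (adjusted p = 0.175 and 0.0637 without wild type 1 and 2, 0.0586 and 0.189 without mE1 1 and 2), without the mE1_CBSmut libraries in the fit (0.0521), with quantile normalization (0.136) and with median-ratio scaling (0.220). PCDHA12 was called higher with both of these scalings (log2 0.47 each, adjusted p = 0.0422 and 0.0462). PCDHAC2 was not called when only the 4 libraries were fitted (adjusted p = 0.0825).

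Genes that fold proteins in the endoplasmic reticulum rose in mE1. HSPA5, the main chaperone of that compartment, rose from 164 ± 9.67 to 1572 ± 37.6 FPKM (log2 3.26, adjusted p = 9.03e-09), HERPUD1, a factor of protein degradation there, from 36.7 ± 1.45 to 159 ± 3.02, and the chaperone HYOU1 from 42.98 ± 2.08 to 156 ± 4.17. In the unfolded protein response list 13 of 15 members rose (13 adjusted over the list alone) and 0 fell (camera, adjusted p = 5.06e-15). The integrated stress response list, genes induced when translation is held back by stress, had 14 of 19 members higher (15 adjusted over the list alone, camera adjusted p = 1.5e-10). In it the transcription factor DDIT3 rose from 10.5 ± 2.18 to 150.4 ± 14.8 FPKM, the pseudokinase TRIB3 from 19.7 ± 2.40 to 139 ± 8.14 and the amino acid transporter SLC7A5 from 45.6 ± 0.596 to 113 ± 3.29.

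Genes of cell division and of sterol synthesis fell in mE1. All 22 tested genes of the mitotic list fell (22 adjusted over the list alone, camera adjusted p = 1.14e-13), among them the topoisomerase TOP2A, from 125 ± 5.27 to 28.2 ± 1.35 FPKM, and BIRC5 (survivin), from 62.7 ± 2.93 to 14.4 ± 0.621. All 19 DNA replication genes fell (19 adjusted over the list alone, camera adjusted p = 1.6e-13). CDC6, which loads the replicative helicase, fell from 37.1 ± 0.314 to 3.10 ± 0.238. The helicase subunit MCM4 fell from 64.1 ± 1.35 to 14.3 ± 0.00438 and MCM6 from 51.6 ± 2.56 to 13.3 ± 0.0467. In the cholesterol synthesis list 21 of 22 members fell (21 adjusted over the list alone, camera adjusted p = 6.2e-10, and adjusted p = 0.230 with an estimated correlation). FDPS, an enzyme of isoprenoid synthesis, fell from 205 ± 0.0341 to 65.7 ± 1.14 FPKM and squalene synthase FDFT1 from 199 ± 23.8 to 61.9 ± 3.17.

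Of the CTCF and cohesin list 10 of 18 members fell and 1 rose (10 and 1 adjusted over the list alone). CTCF itself, the factor that binds the CBS elements, fell from 41.04 ± 0.617 to 24.1 ± 0.202 FPKM (log2 −0.76, adjusted p = 1.33e-05). ESCO2, which acetylates cohesin, fell from 22.8 ± 0.604 to 3.98 ± 0.0149, sororin (CDCA5) from 28.6 ± 1.52 to 6.83 ± 0.629, and the cohesin subunit SMC1A from 21.2 ± 0.935 to 10.4 ± 0.310. RAD21, another cohesin subunit, was at 94.6 ± 2.76 against 120.1 ± 2.35 FPKM (log2 −0.34, adjusted p = 0.000235), a call that was lost with quantile normalization (log2 −0.04) and median-ratio scaling (log2 −0.10). Genes of chromosome 16, where CTCF lies, had a median log2 difference of −0.31 beside that of all genes. The camera call of this list (adjusted p = 0.0441) was lost with an estimated correlation (0.272), without wild type 2 and without mE1 2. Both scalings also ended it (0.373 with quantile normalization, 0.290 with median-ratio scaling).

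Several genes of epithelia and of the extracellular matrix rose in mE1. E-cadherin (CDH1) rose from 0.866 ± 0.255 to 6.70 ± 0.635 FPKM and the tight-junction gene CLDN4 from 6.92 ± 0.322 to 34.3 ± 1.95, while keratin KRT8 fell from 168 ± 12.5 to 96.2 ± 0.297. Of 22 epithelial markers 9 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.00554, and adjusted p = 0.162 with an estimated correlation). In the adhesion and matrix list 14 of 28 rose and 7 fell (14 and 7 adjusted over the list alone, camera adjusted p = 0.000595, and adjusted p = 0.0545 with an estimated correlation). The collagen gene COL4A1 rose from 57.5 ± 4.44 to 189 ± 1.40 and the laminin gene LAMA5 from 38.6 ± 0.926 to 99.8 ± 3.21, while the hyaluronan receptor CD44 fell from 65.1 ± 20.4 to 5.22 ± 0.356. Of 16 immediate early genes 9 rose and 4 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.00111, and adjusted p = 0.133 with an estimated correlation). CYR61, a secreted matrix protein, rose from 22.6 ± 0.594 to 106 ± 0.958 and the transcription factor MYC from 71.5 ± 5.20 to 112 ± 5.70.

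Among single genes, the secreted hormone gene STC1 fell from 52.8 ± 6.46 to 0.157 ± 0.0258 FPKM (log2 −6.34, adjusted p = 1.99e-09), the signalling gene SHH from 21.3 ± 1.02 to 0.915 ± 0.510 and the potassium channel gene KCNMA1 from 41.1 ± 5.83 to 2.18 ± 0.0503. BASP1, a membrane-bound protein of neurons, rose from 0.356 ± 0.322 to 14.1 ± 0.467 (log2 4.14) and SHISA3 from 27.3 ± 1.14 to 306 ± 8.92. Near the protocadherin clusters, PCDHGC3 of the gamma cluster (141476002 to 141512977) fell from 6.23 ± 0.235 to 2.15 ± 0.141, PCDHB8 of the beta cluster from 0.738 ± 0.0377 to 0.149 ± 0.0474, and the neighbours DIAPH1, a formin, from 22.1 ± 0.565 to 10.1 ± 0.506 and HDAC3, a histone deacetylase, from 40.3 ± 2.59 to 25.6 ± 1.06. Of 32 neighbours 9 fell and 4 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.851). Those that rose were APBB3, ARAP3, HBEGF and CYSTM1, named after their values were seen. Of 6 PCDHG genes 2 fell and 1 rose, PCDHGA10, also named afterwards (2 and 1 adjusted over the list alone, camera adjusted p = 0.895), and of 3 PCDHB genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.511). A total of 6807 of 15022 genes were called, 1992 higher and 4815 lower (limma), and the median of all genes was −0.14. The split depended on scaling, with 3282 higher and 3158 lower after quantile normalization and 3356 and 3162 after median-ratio scaling.

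**Figure D2:**
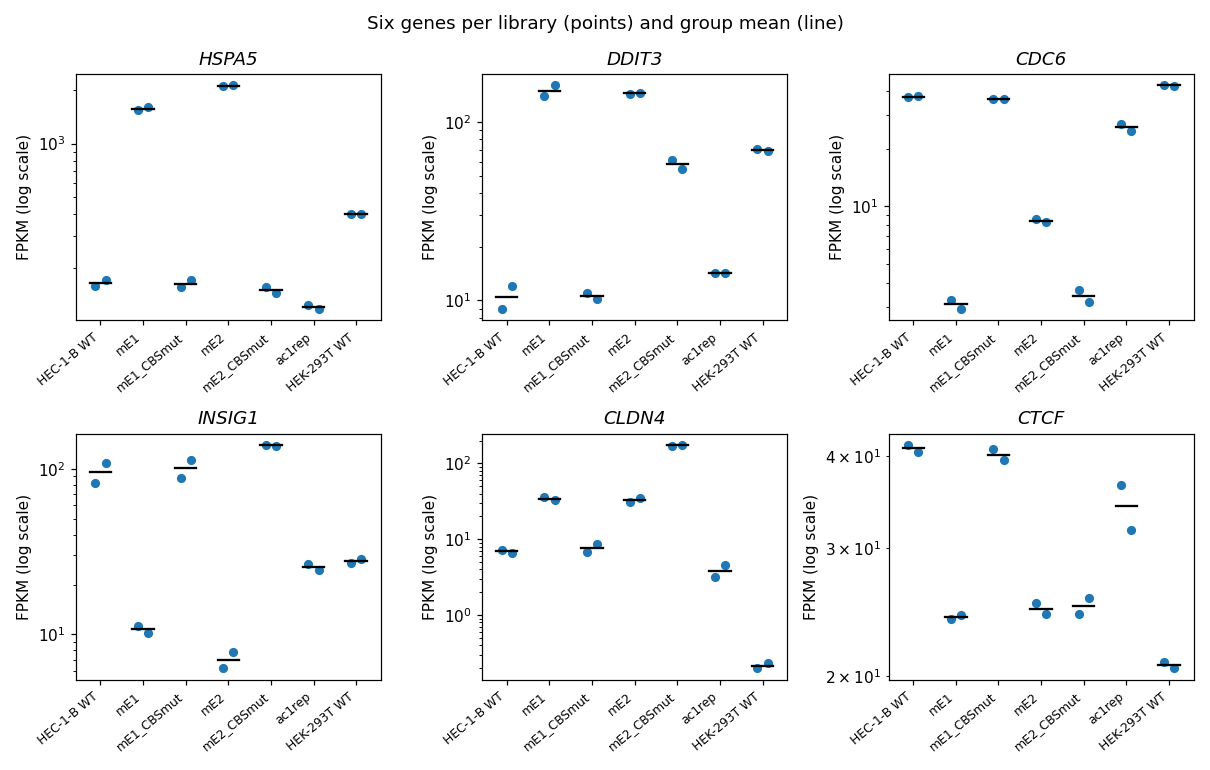
FPKM (vertical axis, log scale) of HSPA5, DDIT3, CDC6, INSIG1, CLDN4 and CTCF, 1 panel each, in the 7 groups (horizontal axis), with a point for each of the 2 libraries and a line at their mean. HSPA5 was at 1572 and 2116 FPKM in mE1 and mE2 and at 164, 163 and 150.1 in wild type, mE1_CBSmut and mE2_CBSmut.

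mE1_CBSmut was set against mE1, which differs over whole chromosome stretches (below). PCDHA6 rose from 1.79 ± 0.216 to 3.06 ± 0.0739 FPKM (log2 0.64, adjusted p = 0.00921) and PCDHAC2 from 1.42 ± 0.461 to 2.63 ± 0.154 (log2 0.73, adjusted p = 0.00648). PCDHAC1 was at 1.67 ± 0.747 (log2 0.66, adjusted p = 0.0698) with libraries at 1.15 and 2.20 FPKM, and PCDHA12 was at 3.71 ± 0.558 (log2 −0.36, adjusted p = 0.141). Of the 4 genes 2 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.678). Without mE1 2 the PCDHA6 call was lost (adjusted p = 0.0645), without mE1 1 the PCDHAC2 call (0.0511), and without mE1_CBSmut 1 PCDHAC1 was called (log2 1.02, adjusted p = 0.0175), as it was without the ac1rep libraries in the fit (adjusted p = 0.0415). Median-ratio scaling ended the PCDHA6 call (0.0564), and PCDHA12 was called lower with quantile normalization (log2 −0.57, adjusted p = 0.0194) and median-ratio scaling (log2 −0.58, adjusted p = 0.0202).

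Chaperone genes fell and division genes rose in mE1_CBSmut relative to mE1. HSPA5 fell to 163 ± 10.8 FPKM (log2 −3.27), DDIT3 to 10.6 ± 0.664 and TRIB3 to 20.8 ± 1.48. In the unfolded protein response list 13 of 15 members fell (13 adjusted over the list alone, camera adjusted p = 3.37e-15), and in the integrated stress response list 14 of 19 (14 adjusted over the list alone, camera adjusted p = 2.01e-10). Of 22 mitotic genes 21 rose (22 adjusted over the list alone, camera adjusted p = 1.24e-13) and of 19 replication genes 19 rose (19 adjusted over the list alone, camera adjusted p = 1.52e-13). TOP2A was at 126 ± 3.28 and CDC6 at 36.04 ± 0.113 FPKM. In the cholesterol list 21 of 22 rose (21 adjusted over the list alone, camera adjusted p = 6.24e-10, and adjusted p = 0.230 with an estimated correlation), among them INSIG1, a regulator of sterol sensing, from 10.8 ± 0.752 to 100.3 ± 17.7. CTCF rose to 40.2 ± 0.970 FPKM (log2 0.73, adjusted p = 1.68e-05), and RAD21 was at 117 ± 0.369 (log2 0.30, adjusted p = 0.000539), with a sign that turned after quantile normalization (log2 −0.02).

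In mE1_CBSmut relative to mE1, 10 of 18 CTCF and cohesin genes rose and 1 fell (11 and 1 adjusted over the list alone). The camera call of that list (adjusted p = 0.0455, and adjusted p = 0.237 with an estimated correlation) was also lost without mE1 2 (0.117), without mE1_CBSmut 2 (0.0602), with quantile normalization (0.352) and with median-ratio scaling (0.291). Epithelial markers fell in 10 and rose in 4 of 22 cases (11 and 5 adjusted over the list alone, camera adjusted p = 0.00185, and adjusted p = 0.114 with an estimated correlation). Immediate early genes fell in 9 and rose in 4 of 16 cases (10 and 4 adjusted over the list alone, camera adjusted p = 0.000799, and adjusted p = 0.114 with an estimated correlation). Adhesion and matrix genes fell in 14 and rose in 7 of 28 cases (14 and 7 adjusted over the list alone, camera adjusted p = 0.000799, and adjusted p = 0.0619 with an estimated correlation). STC1 rose to 51.8 ± 3.88, and PCDHGC3 rose to 6.70 ± 0.916. The count was 6792 genes, 4817 higher and 1975 lower, with a median of all genes of 0.14, and it became 3142 and 3349 after quantile normalization and 3207 and 3351 after median-ratio scaling.

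mE1_CBSmut was also set against wild-type HEC-1-B. CYCSP52, a processed pseudogene of cytochrome c whose reads may belong to its parent gene, was listed at 0 in both wild-type libraries and measured at 2.16 and 1.87 FPKM (adjusted p = 0.000678). The 4 PCDHA genes differed by log2 0.17 (PCDHA6), −0.10 (PCDHA12), −0.02 (PCDHAC1) and −0.05 (PCDHAC2), with an adjusted p of 1 each, and 0 were called adjusted over the list alone (limma). CTCF was at 40.2 ± 0.970 against 41.04 ± 0.617 FPKM and RAD21 at 117 ± 0.369 against 120.1 ± 2.35. The test called 3 genes (2 higher, 1 lower), which besides CYCSP52 were LOC102724719 and SNORA41, named after their values were seen, and 370 genes had an unadjusted p under 0.05. Leaving out 1 library gave 4 to 6 genes, and camera called 0 lists (lowest adjusted p = 0.921). Without 1 of the 4 libraries camera called cholesterol genes (adjusted p = 8.12e-07 to 0.0174) and ribosomal protein genes (0.000136 to 0.00583), each higher in 2 fits and lower in the other 2, fibroblast markers in 1 fit (lower, 0.036) and immune markers in 1 (higher, 0.0277).

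mE2 was set against the same wild-type libraries, whose chance values it shares with the mE1 comparison. PCDHAC2 fell from 2.73 ± 0.0509 to 0.976 ± 0.157 FPKM (log2 −1.13, adjusted p = 0.000501) and PCDHA6 rose from 2.66 ± 0.240 to 3.84 ± 0.133 (log2 0.46, adjusted p = 0.0390). PCDHA12 was at 4.30 ± 0.858 (log2 0.08, adjusted p = 0.755) and PCDHAC1 at 0.964 ± 0.125 (log2 −0.55, adjusted p = 0.122), so that 1 gene rose and 1 fell (1 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.818). The 53 expressed genes within 5 Mb of the cluster had a median log2 difference of −0.34 beside that of all genes, and those of chromosome 5 from 60 Mb on −0.36. The PCDHA6 call was lost without any 1 of the 4 libraries (adjusted p = 0.0654 and 0.172 without wild type 1 and 2, 0.0900 and 0.129 without mE2 1 and 2), without the mE1_CBSmut libraries in the fit (0.0528) and with quantile normalization (0.0979).

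Endoplasmic reticulum and stress genes rose in mE2, and division and sterol genes fell. HSPA5 rose from 164 ± 9.67 to 2116 ± 16.5 FPKM (log2 3.69, adjusted p = 3.09e-09), HYOU1 from 42.98 ± 2.08 to 264 ± 7.81 and DDIT3 from 10.5 ± 2.18 to 145 ± 1.13, and SLC3A2, the heavy chain of amino acid transporters, from 66.05 ± 3.83 to 284 ± 18.5. The unfolded protein response list had 14 of 15 members higher (14 adjusted over the list alone, camera adjusted p = 8.91e-13). The integrated stress response list had 16 of 19 higher (16 adjusted over the list alone, camera adjusted p = 2.58e-08, and adjusted p = 0.0555 with an estimated correlation). All 22 mitotic genes fell (22 adjusted over the list alone, camera adjusted p = 1.28e-15). The cyclin CCNA2 fell from 24.7 ± 0.427 to 6.22 ± 0.196. Of 19 replication genes 18 fell (18 lower and 1 higher adjusted over the list alone, camera adjusted p = 8.91e-13). RRM1, a subunit of ribonucleotide reductase, fell from 47.2 ± 0.692 to 14.1 ± 0.270. In the cholesterol list 21 of 22 fell (21 adjusted over the list alone, camera adjusted p = 2.6e-11, and adjusted p = 0.289 with an estimated correlation). INSIG1 fell from 95.3 ± 18.8 to 7.02 ± 1.12.

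Immediate early genes fell in 9 and rose in 3 of 16 cases in mE2 (9 and 3 adjusted over the list alone). The transcription factor EGR1 fell from 43.8 ± 3.98 to 4.74 ± 0.0385 FPKM and JUN from 34.4 ± 2.55 to 18.3 ± 1.12. The camera call (adjusted p = 0.0475, and adjusted p = 0.404 with an estimated correlation) was lost without wild type 2 (0.0793), without mE2 1 (0.0930), with quantile normalization (0.0882) and with median-ratio scaling (0.0592). Of 32 genes that neighbour the clusters 18 fell and 2 rose (19 and 3 adjusted over the list alone, camera adjusted p = 0.00966, and adjusted p = 0.459 with an estimated correlation), beside the shift of chromosome 5 given above. HARS, a histidyl-tRNA synthetase, fell from 27.2 ± 3.26 to 13.9 ± 0.961 FPKM, SLC35A4 from 29.1 ± 0.0724 to 17.01 ± 0.0605 and PCDHGC3 from 6.23 ± 0.235 to 0.807 ± 0.258. CTCF fell to 24.8 ± 0.603 FPKM (log2 −0.72, adjusted p = 2.01e-05), while genes of chromosome 16 had a median of 0.14 beside that of all genes, and RAD21 was at 92.8 ± 2.86 (log2 −0.37, adjusted p = 0.000150), a call lost with quantile normalization (log2 −0.05).

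The cell-cycle inhibitor gene CDKN2A on chromosome 9 fell from 47.8 ± 10.3 FPKM in wild type to 0.121 ± 0.0576 in mE2 (log2 −6.27, adjusted p = 2.45e-08), and MSMP on the same chromosome from 92.2 ± 26.2 to 2.87 ± 0.529. The somatostatin gene SST fell from 460.0 ± 21.1 to 11.3 ± 0.220 FPKM (log2 −5.28, adjusted p = 3.41e-10). The laminin gene LAMA3 rose from 4.52 ± 0.305 to 81.2 ± 6.85, the elongation factor gene EEF1A2 from 1.95 ± 0.243 to 37.4 ± 4.85, CDH1 to 12.5 ± 1.65 and EHF, an epithelial transcription factor, from 1.37 ± 0.0198 to 13.8 ± 2.33. The test called 7032 genes, 3361 higher and 3671 lower, against 3551 and 3301 after quantile normalization. RMRP and RPPH1, which met the naming rule here or in other comparisons, make RNAs without a poly(A) tail and are not described further.

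mE2_CBSmut was set against mE2, which differs over whole chromosome stretches (below). PCDHA6 fell from 3.84 ± 0.133 to 1.95 ± 0.196 FPKM (log2 −0.83, adjusted p = 0.00315) and PCDHAC2 rose from 0.976 ± 0.157 to 2.44 ± 0.276 (log2 0.99, adjusted p = 0.00163). PCDHA12 was at 4.36 ± 0.753 (log2 0.02, adjusted p = 0.974) and PCDHAC1 at 1.53 ± 0.110 (log2 0.47, adjusted p = 0.201), which left 1 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.759). Genes within 5 Mb of the cluster had a median of 0.44, and those of chromosome 16 −0.41, beside that of all genes. CTCF was at 24.96 ± 0.861 FPKM (log2 0.01, adjusted p = 0.936), and RAD21 rose to 111 ± 2.12 (log2 0.26, adjusted p = 0.00176).

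Sterol, interferon and epithelial genes rose in mE2_CBSmut relative to mE2. In the cholesterol list 21 of 22 rose (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.49e-17, and adjusted p = 0.0803 with an estimated correlation). The synthase HMGCS1 rose from 16.9 ± 1.69 to 155 ± 14.6 FPKM. Of 23 interferon response genes 18 rose (21 adjusted over the list alone, camera adjusted p = 3.01e-10). The RNA sensor DDX58 (RIG-I) rose from 3.05 ± 0.235 to 9.18 ± 0.178 and ISG15 from 13.6 ± 0.817 to 45.96 ± 0.661. Epithelial markers rose in 19 and fell in 1 of 22 cases (19 and 1 adjusted over the list alone, camera adjusted p = 3.01e-10). CLDN4 rose from 32.7 ± 2.70 to 174 ± 2.85 and the splicing regulator ESRP1 from 0.356 ± 0.0918 to 4.96 ± 0.698. Mitotic genes rose in 17 and fell in 2 of 22 cases (17 and 2 adjusted over the list alone, camera adjusted p = 2.38e-07). The kinesin KIF20A rose from 6.38 ± 0.931 to 33.8 ± 3.16. Immediate early genes rose in 12 of 16 cases (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.12e-07). EGR1 rose to 33.04 ± 0.344.

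The unfolded protein response list fell in mE2_CBSmut relative to mE2 for all 15 members (15 adjusted over the list alone, camera adjusted p = 2.76e-16). HSPA5 fell to 150.1 ± 7.08 FPKM and the chaperone CALR from 1131 ± 45.6 to 186 ± 0.187. Integrated stress response genes fell in 11 of 19 cases (12 adjusted over the list alone, camera adjusted p = 0.000352, and adjusted p = 0.151 with an estimated correlation). NUPR1, a stress-induced chromatin protein, fell from 157 ± 19.4 to 18.2 ± 1.71. Of 31 ribosomal protein genes 9 fell (7 adjusted over the list alone). RPL14 fell from 615 ± 37.6 to 421 ± 25.2 and RPL19 from 1352 ± 28.5 to 945 ± 29.4. The camera call (adjusted p = 0.00241) was lost with an estimated correlation (adjusted p = 0.689 with an estimated correlation) and with quantile normalization (0.0502). Adhesion and matrix genes rose in 13 and fell in 5 of 28 cases (15 and 5 adjusted over the list alone, camera adjusted p = 0.00185, and adjusted p = 0.0719 with an estimated correlation). N-cadherin (CDH2) rose from 2.65 ± 0.249 to 15.3 ± 0.106 and ALCAM fell from 103 ± 5.28 to 44.6 ± 0.667. Neighbours of the clusters rose in 14 and fell in 6 of 32 cases (19 and 7 adjusted over the list alone, camera adjusted p = 0.00611, and adjusted p = 0.488 with an estimated correlation). HARS2 rose from 6.28 ± 0.467 to 13.1 ± 0.923 and PCDH1, a protocadherin outside the clusters, fell from 36.3 ± 1.34 to 20.1 ± 0.796. CDKN2A rose to 28.2 ± 5.17 FPKM, BASP1 from 0.135 ± 0.112 to 49.03 ± 1.78, the desaturase SCD from 15.9 ± 0.563 to 389.6 ± 2.64 and PCDHGC3 to 3.62 ± 0.338, and the test called 5453 genes, 2569 higher and 2884 lower. Median-ratio scaling turned the majority, with 3025 higher and 2410 lower, as did removal of the GC and length trend (2917 and 2537).

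Against wild-type HEC-1-B, mE2_CBSmut had 0 PCDHA genes called by limma over all genes or adjusted over the list alone. PCDHA6 was at 1.95 ± 0.196 FPKM (log2 −0.37, adjusted p = 0.0911) and was called lower after quantile normalization (log2 −0.46, adjusted p = 0.0394), PCDHA12 differed by log2 0.10 (adjusted p = 0.696), PCDHAC1 by −0.07 (adjusted p = 0.867) and PCDHAC2 by −0.14 (adjusted p = 0.553), and camera gave the list an adjusted p of 0.747. CTCF fell from 41.04 ± 0.617 to 24.96 ± 0.861 FPKM (log2 −0.71, adjusted p = 2.4e-05), where genes of chromosome 16 had a median of −0.26 beside that of all genes, and RAD21 was at 111 ± 2.12 (log2 −0.11, adjusted p = 0.0837), with a sign that turned after quantile normalization (log2 0.15).

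Epithelial markers rose in 16 of 22 cases in mE2_CBSmut against wild type (16 adjusted over the list alone, camera adjusted p = 1.54e-09). CLDN4 rose from 6.92 ± 0.322 to 174 ± 2.85 FPKM (log2 4.56), CDH1 from 0.866 ± 0.255 to 19.6 ± 1.11 and the protease ST14 from 0.171 ± 0.106 to 19.4 ± 0.130. ESRP1 was listed at 0 in both wild-type libraries and measured at 5.45 and 4.46 FPKM. Interferon response genes rose in 17 and fell in 1 of 23 cases (18 and 1 adjusted over the list alone, camera adjusted p = 1.78e-07). IFIT1 rose from 3.44 ± 0.0534 to 18.8 ± 0.570 and the transcription factor STAT2 from 5.06 ± 0.377 to 14.9 ± 0.102. All 19 replication genes fell (19 adjusted over the list alone, camera adjusted p = 4.27e-14) and 20 of 22 mitotic genes fell (20 adjusted over the list alone, camera adjusted p = 1.54e-09). CDC6 was at 3.42 ± 0.344 and TOP2A at 38.8 ± 2.09. Integrated stress response genes rose in 13 and fell in 1 of 19 cases (13 and 1 adjusted over the list alone, camera adjusted p = 6.83e-05, and adjusted p = 0.153 with an estimated correlation).

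In the same comparison 13 of 28 adhesion and matrix genes rose and 7 fell (13 and 7 adjusted over the list alone, camera adjusted p = 0.0154, and adjusted p = 0.153 with an estimated correlation). The integrin gene ITGB4 rose from 28.3 ± 1.92 to 150.5 ± 4.30 FPKM. The cholesterol list had 13 of 22 members higher and 1 lower (13 and 1 adjusted over the list alone). CYP51A1, an enzyme of sterol synthesis, rose from 51.5 ± 8.11 to 100.1 ± 9.02. Its camera call (adjusted p = 0.00189, and adjusted p = 0.546 with an estimated correlation) was lost without wild type 1 (0.0552). The acute-phase gene SAA1 rose from 0.804 ± 0.231 to 91.2 ± 2.33 FPKM (log2 6.15), the calcium-binding gene S100A14 from 1.56 ± 0.994 to 57.1 ± 7.79, and the protease inhibitor SERPINE2 fell from 29.7 ± 1.08 to 1.28 ± 0.136. PCDHB3 fell from 0.764 ± 0.251 to 0.106 ± 0.0307, and the neighbours PCDH1 and GNPDA1 from 35.5 ± 0.897 to 20.1 ± 0.796 and from 54.2 ± 0.277 to 33.1 ± 3.22, while the neighbour IGIP rose from 4.43 ± 0.731 to 9.83 ± 0.195. Of 32 neighbours 9 fell and 9 rose (9 and 9 adjusted over the list alone, camera adjusted p = 0.747), and all 3 tested PCDHB genes fell (3 adjusted over the list alone, camera adjusted p = 0.136). The test called 6812 genes, 2980 higher and 3832 lower, against 3530 and 3253 after median-ratio scaling and 843 and 750 at a fold change of at least 2.

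The difference between mE1_CBSmut and mE1 was tested against that between mE2_CBSmut and mE2, as the first minus the second. PCDHA6 differed by log2 1.46 (adjusted p = 0.000644), since it was higher in mE1_CBSmut than in mE1 and lower in mE2_CBSmut than in mE2. PCDHA12, PCDHAC1 and PCDHAC2 differed by −0.38 (adjusted p = 0.270), 0.19 (adjusted p = 0.737) and −0.27 (adjusted p = 0.413), none of them called, and 1 PCDHA gene was called adjusted over the list alone (camera adjusted p = 0.913). CTCF differed by 0.72 (adjusted p = 0.000201). RAD21 differed by 0.04 (adjusted p = 0.708) and was called lower with median-ratio scaling (−0.27, adjusted p = 0.0107) and with the GC and length trend removed (−0.24, adjusted p = 0.0259). CDC6 differed by 4.53 and TOP2A by 2.59, with 18 of 19 replication genes (19 adjusted over the list alone, camera adjusted p = 1.79e-11) and 19 of 22 mitotic genes (19 adjusted over the list alone, camera adjusted p = 4.91e-06) higher in the difference. CLDN4 differed by −4.48, CYR61 by −2.86 and COL4A1 by −2.48. Epithelial markers were lower in the difference in 16 of 22 cases (16 adjusted over the list alone, camera adjusted p = 7.67e-10), immediate early genes in 13 of 16 (13 adjusted over the list alone, camera adjusted p = 3.83e-09), interferon response genes in 16 of 23 (17 adjusted over the list alone, camera adjusted p = 1.96e-08) and adhesion and matrix genes in 16 of 28 (16 adjusted over the list alone, camera adjusted p = 4.91e-06).

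In the same test the integrated stress response list was lower in 11 of 19 members (11 adjusted over the list alone, camera adjusted p = 0.000351, and adjusted p = 0.151 with an estimated correlation). Neighbours of the clusters were lower in 16 and higher in 9 of 32 cases (17 and 9 adjusted over the list alone, camera adjusted p = 0.0183, and adjusted p = 0.470 with an estimated correlation). DIAPH1 differed by 1.43 and CYSTM1 by −1.42. Cholesterol genes were lower in 11 and higher in 5 of 22 cases (11 and 6 adjusted over the list alone). The camera call (adjusted p = 0.00861, and adjusted p = 0.507 with an estimated correlation) was lost without mE1_CBSmut 1 (0.0512). The hypoxia list had 11 of 21 members higher and 1 lower (11 and 2 adjusted over the list alone). The camera call of this list (adjusted p = 0.0488, and adjusted p = 0.137 with an estimated correlation) was lost without any 1 of 6 libraries (both mE1_CBSmut and both mE2_CBSmut libraries, mE1 2 and mE2 2), at adjusted p between 0.0512 and 0.0874, and with quantile normalization (0.160) and median-ratio scaling (0.131). A total of 6436 genes were called, 4406 higher and 2030 lower, with a median of all genes of 0.19, and the split was 3134 and 3032 after quantile normalization and 2856 and 3338 after median-ratio scaling.

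The ac1 repeat was set against wild-type HEC-1-B. PCDHA12 fell from 4.02 ± 0.639 to 1.07 ± 0.190 FPKM (log2 −1.52, adjusted p = 7.07e-05), PCDHAC1 from 1.64 ± 0.263 to 0.287 ± 0.257 (log2 −1.48, adjusted p = 0.000949) and PCDHAC2 from 2.73 ± 0.0509 to 1.12 ± 0.149 (log2 −0.997, adjusted p = 0.000700), beside a median of all genes of −0.36. PCDHA6 was at 2.09 ± 0.585 FPKM (log2 −0.30, adjusted p = 0.135) and was called lower without ac1rep 2 (log2 −0.54, adjusted p = 0.0150). Its sign turned with quantile normalization (0.37) and median-ratio scaling (0.12), and the PCDHAC2 call was lost with quantile normalization (log2 −0.32, adjusted p = 0.159). Of the 4 genes 3 fell (3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.447). The ac1rep values were made in a different way from those of the other libraries, and their difference from wild type followed the GC content of genes. Over 5 equal groups of genes with a mean of at least 10 FPKM, the median log2 difference was −0.84 in the group with the lowest GC content and 0.17 in that with the highest.

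Immediate early genes rose in 9 and fell in 2 of 16 cases in ac1rep (9 and 2 adjusted over the list alone, camera adjusted p = 2.48e-06, and adjusted p = 0.139 with an estimated correlation). CYR61 rose from 22.6 ± 0.594 to 111 ± 2.05 FPKM and JUN from 34.4 ± 2.55 to 102 ± 3.80. Adhesion and matrix genes fell in 21 and rose in 2 of 28 cases (21 and 2 adjusted over the list alone, camera adjusted p = 0.00716, and adjusted p = 0.240 with an estimated correlation). The laminin gene LAMC1 fell from 419 ± 14.8 to 123 ± 0.148 and CDH2 from 10.2 ± 1.52 to 1.13 ± 0.0842. Of 18 CTCF and cohesin genes 15 fell and 2 rose (15 and 2 adjusted over the list alone, camera adjusted p = 0.0237, and adjusted p = 0.331 with an estimated correlation), a call lost with median-ratio scaling (0.0864). In that list RAD21 fell from 120.1 ± 2.35 to 39.7 ± 1.66 and the cohesin subunit STAG2 from 17.5 ± 0.423 to 5.11 ± 0.0717, while CTCF was at 34.2 ± 3.44 (log2 −0.26, adjusted p = 0.00571), lower as deposited but higher with median-ratio scaling (log2 0.24, adjusted p = 0.0118). Replication histone genes rose in 3 of 18 cases (2 adjusted over the list alone). HIST1H2BK rose from 17.8 ± 1.03 to 33.1 ± 1.69. The camera call (adjusted p = 0.00203, and adjusted p = 0.240 with an estimated correlation) was lost with median-ratio scaling (0.130). Most such histone transcripts lack a poly(A) tail, so these libraries measure them poorly.

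Epithelial markers in ac1rep rose in 8 and fell in 7 of 22 cases (8 and 7 adjusted over the list alone). KRT8 rose from 168 ± 12.5 to 376 ± 4.53 FPKM and the membrane trafficking gene MAL2 fell from 172 ± 16.5 to 30.2 ± 2.13. For this list camera gave the direction up (adjusted p = 0.0259, and adjusted p = 0.331 with an estimated correlation) with a median of 0.09 and a mean of −0.17, and the call was lost without ac1rep 2 (0.10), with quantile normalization (0.295) and with median-ratio scaling (0.195). The actin-bundling gene FSCN1 rose from 2.54 ± 0.250 to 44.6 ± 0.889 and ANKRD1 from 0.373 ± 0.0433 to 9.30 ± 0.0976, and the actin-severing gene SCIN was at 0 and 0.119 FPKM in the ac1rep libraries against 31.6 ± 4.80 in wild type. RPL21P28, HNRNPA1P10, FTH1P3, RPS26P11, RPS14P3, ATP5EP2 and ANP32AP1, pseudogenes or close copies whose reads can be assigned to either copy, and CLIC1, BAG6, RNF5 and PRRC2A, which also lie on alternate sequences of chromosome 6, met the naming rule too and are uncertain in these files. PCDHGB5 fell from 3.16 ± 0.466 to 1.44 ± 0.176 FPKM, a call lost with quantile normalization, and the neighbours PCDH1 and CXXC5 fell from 35.5 ± 0.897 to 20.3 ± 0.218 and from 20.6 ± 1.47 to 10.4 ± 0.00722. Of 32 neighbours 19 fell and 4 rose (19 and 4 adjusted over the list alone, camera adjusted p = 0.884), the latter being HARS, ZMAT2, EIF4EBP3 and PFDN1, named after their values were seen. The test called 8565 genes, 1566 higher and 6999 lower, against 3721 and 3752 after quantile normalization and 4090 and 4152 after median-ratio scaling.

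The unedited lines differed at 10423 genes, 6182 higher and 4241 lower in HEK-293T, which was grown in another medium, with a median of all genes of 0.16 (4933 and 5037 with the GC and length trend removed). All 4 PCDHA genes were lower in HEK-293T (4 adjusted over the list alone, camera adjusted p = 0.00661, and adjusted p = 0.0794 with an estimated correlation). Epithelial markers were lower in 16 and higher in 1 of 22 cases (16 and 1 adjusted over the list alone, camera adjusted p = 5.32e-07). Keratin KRT19 was at 0.605 ± 0.388 against 379 ± 17.5 FPKM. HEK-293T markers were higher in 17 and lower in 4 of 21 cases (17 and 4 adjusted over the list alone, camera adjusted p = 0.000828). The neurofilament gene NEFM was at 54.7 and 53.9 FPKM and listed at 0 in both HEC-1-B libraries. Adhesion and matrix genes were lower in 21 and higher in 6 of 28 cases (21 and 6 adjusted over the list alone, camera adjusted p = 3.49e-06). The integrin gene ITGA3 was at 2.06 ± 0.260 against 300.4 ± 31.7. SPP1 (osteopontin) was at 0.876 ± 0.156 against 833 ± 4.93, the ubiquitin gene UBB at 830.3 ± 4.27 against 0.607 and 0.175, and SST was listed at 0 in both HEK-293T libraries and at 460.0 ± 21.1 in HEC-1-B.

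Stress and metabolic lists also differed between the unedited lines. Unfolded protein response genes were higher in HEK-293T in 12 of 15 cases (13 adjusted over the list alone, camera adjusted p = 0.00301, and adjusted p = 0.200 with an estimated correlation). Integrated stress response genes were higher in 13 and lower in 4 of 19 cases (13 and 4 adjusted over the list alone, camera adjusted p = 0.0374, and adjusted p = 0.370 with an estimated correlation). Hypoxia genes were higher in 17 and lower in 2 of 21 cases (17 and 2 adjusted over the list alone, camera adjusted p = 0.00661, and adjusted p = 0.0721 with an estimated correlation). Cholesterol genes were lower in 19 and higher in 3 of 22 cases (19 and 3 adjusted over the list alone, camera adjusted p = 2.77e-05, and adjusted p = 0.370 with an estimated correlation). Immediate early genes were lower in 9 and higher in 3 of 16 cases (9 and 3 adjusted over the list alone, camera adjusted p = 0.0330, and adjusted p = 0.255 with an estimated correlation). Replication genes were higher in 13 of 19 cases (13 adjusted over the list alone). The camera call (adjusted p = 0.0330, and adjusted p = 0.370 with an estimated correlation) was lost without wild-type HEC-1-B 2 (0.0535) and with median-ratio scaling (0.0524).

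Against HEK-293T, ac1rep differed at 11436 genes, 2916 higher and 8520 lower (5250 and 5613 after quantile normalization, 5112 and 5822 after median-ratio scaling), with a median of all genes of −0.59, and both the cell line and the way the values were made differ in this comparison. Of the 4 PCDHA genes 3 were higher over all genes and 4 adjusted over the list alone, and the camera call (adjusted p = 0.00623, and adjusted p = 0.0693 with an estimated correlation) was lost with median-ratio scaling (0.0574). PCDHAC1 was at 0.469 and 0.105 FPKM in ac1rep and was called without ac1rep 2 (adjusted p = 0.0124). Epithelial markers were higher in 15 and lower in 1 of 22 cases (15 and 1 adjusted over the list alone, camera adjusted p = 1.4e-09). KRT18 was at 499 ± 6.42 against 27.9 ± 0.0523 FPKM. Adhesion and matrix genes were higher in 21 and lower in 7 of 28 cases (21 and 7 adjusted over the list alone, camera adjusted p = 1.06e-06). Immediate early genes were higher in 11 and lower in 3 of 16 cases (11 and 3 adjusted over the list alone, camera adjusted p = 3.51e-06, and adjusted p = 0.0599 with an estimated correlation). HEK-293T markers were lower in 18 and higher in 3 of 21 cases (18 and 3 adjusted over the list alone, camera adjusted p = 0.00631, and adjusted p = 0.0661 with an estimated correlation). UCHL1 was listed at 0 in both ac1rep libraries and at 151 ± 3.94 in HEK-293T.

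Stress lists were lower in ac1rep than in HEK-293T. Unfolded protein response genes were lower in 14 of 15 cases (14 adjusted over the list alone, camera adjusted p = 0.0122, and adjusted p = 0.235 with an estimated correlation), a call lost with median-ratio scaling (0.111). Integrated stress response genes were lower in 16 and higher in 2 of 19 cases (16 and 2 adjusted over the list alone, camera adjusted p = 0.0106, and adjusted p = 0.271 with an estimated correlation). Hypoxia genes were lower in 18 and higher in 2 of 21 cases (19 and 2 adjusted over the list alone, camera adjusted p = 0.0139, and adjusted p = 0.0762 with an estimated correlation). Cholesterol genes were higher in 10 and lower in 5 of 22 cases (10 and 5 adjusted over the list alone, camera adjusted p = 0.00326, and adjusted p = 0.394 with an estimated correlation). Interferon response genes were higher in 8 and lower in 6 of 23 cases (8 and 6 adjusted over the list alone). Their median was 0.21 and their mean −0.11, and the camera call (up, adjusted p = 0.0459, and adjusted p = 0.155 with an estimated correlation) was lost without ac1rep 1 (0.0760), without HEK-293T 1 (0.0562) and with median-ratio scaling (0.184). Replication histone genes were higher in 4 and lower in 2 of 18 cases (3 and 2 adjusted over the list alone). The camera call (adjusted p = 0.0452, and adjusted p = 0.271 with an estimated correlation) was lost without ac1rep 1, without HEK-293T 1 (adjusted p = 0.0591 and 0.0562) and with both scalings (0.140 with quantile normalization, 0.210 with median-ratio scaling).

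The other lists were not called by camera in any of the 10 comparisons. Their lowest adjusted p values were 0.0534 for endometrial genes, 0.0774 for mesenchymal genes, 0.0889 for PCDHB genes, 0.0967 for DNA methylation genes, 0.0989 for p53 targets, 0.138 for other protocadherins, 0.218 for immune markers, 0.226 for fibroblast markers, 0.251 for Wnt targets and 0.283 for PCDHG genes. Endothelial markers, with 2 tested genes, and mitochondrial transcripts could not be tested. Other settings called endometrial genes in ac1rep against HEK-293T (0.042 to 0.0487) and mesenchymal genes between the unedited lines (0.0277 to 0.0498).

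Genes of whole chromosome stretches differed together in mE1, mE2, mE2_CBSmut and ac1rep, as summarised over 141 bins of 20 Mb. The stretches named here were chosen after the bin medians were seen, and medians are given after subtracting that of all genes. In mE2 against wild type, 116 expressed genes of chromosome 9 below 40 Mb had a median log2 difference of −0.79 (−0.73 and −0.85 for the library pairs of number 1 and 2), with 90.5% of genes below the median of all genes, and genes of chromosome 12 had −0.32. In mE2_CBSmut against wild type chromosome 9 below 40 Mb stood at −0.20, and against mE2 at 0.64. In mE1 the medians were −0.31 on chromosome 16, −0.35 on chromosome 17 from 40 Mb on and −0.37 on chromosome 6 below 130 Mb. In mE2_CBSmut they were −0.26, −0.37 and −0.31, closer to mE1 than to mE2 (0.14, −0.08 and 0.003). The SD of the bin medians was 0.156 in mE1, 0.185 in mE2 and 0.164 in mE2_CBSmut, above all 1000 shuffles of gene positions, and 0.0155 in mE1_CBSmut, where 13 of 1000 shuffles were as high. For mE2_CBSmut against mE2 it was 0.215 and for ac1rep against wild type 0.320, also above all 1000 shuffles (highest 0.0849 and 0.151), and with the GC and length trend removed these became 0.212 and 0.184.

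**Figure D3:**
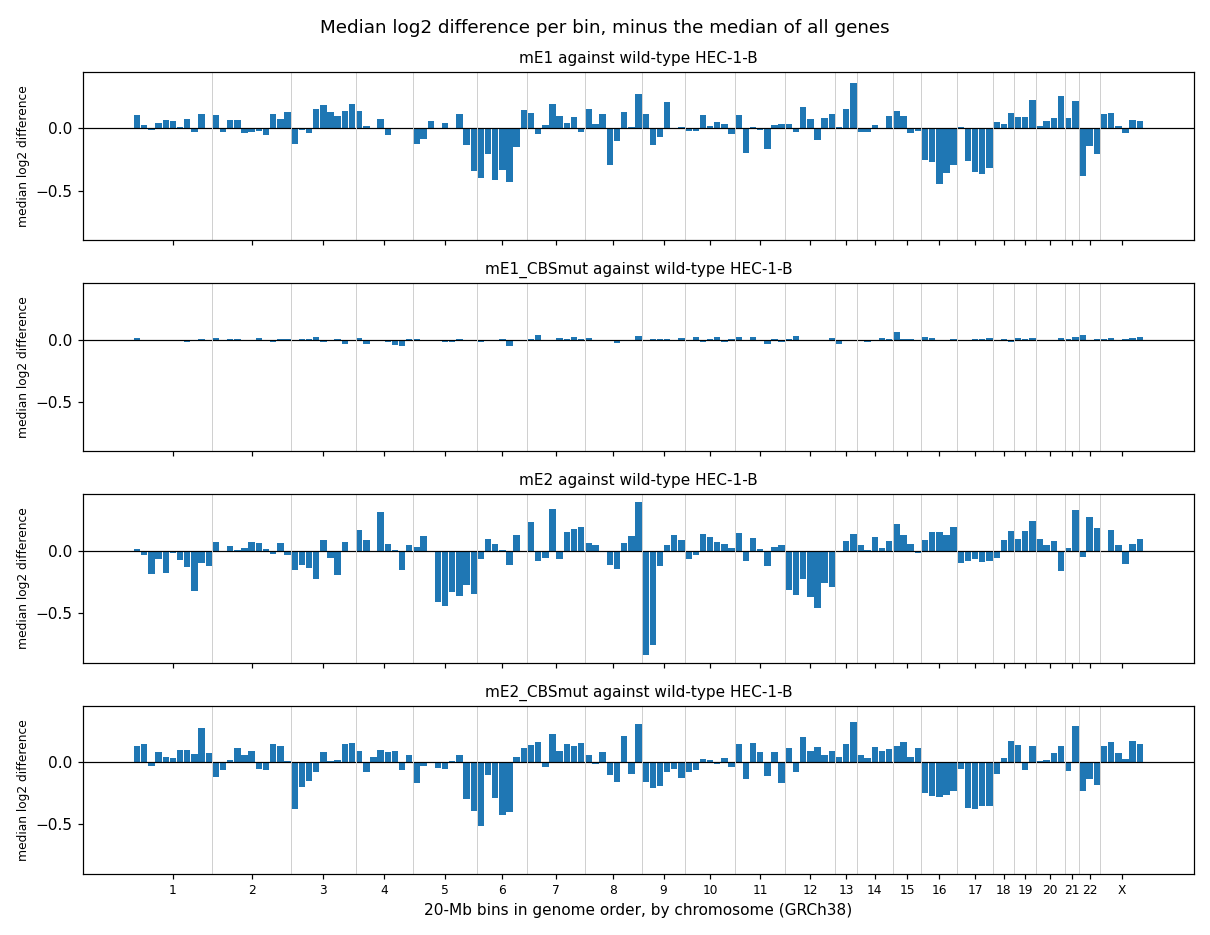
Median log2 difference from wild-type HEC-1-B of the genes in each 20-Mb bin, less the median of all genes (vertical axis), in genome order by chromosome (horizontal axis), with 1 bar per bin and 1 panel each for mE1, mE1_CBSmut, mE2 and mE2_CBSmut. The bars of mE1_CBSmut lie between −0.05 and 0.06, and those of mE1 between −0.44 and 0.36.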

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

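All tests of why mE1_CBSmut lies close to wild type were chosen only after the result was seen. mE2_CBSmut differs from mE2 over whole stretches (SD of bin medians 0.215), so the changed CBS is not isolated. Each result here stands because the planned limma test found mE1_CBSmut minus mE1 unlike mE2_CBSmut minus mE2 (log2, first minus second). It called 6436 genes, 42.8% of those tested, and 88 of the 101 genes named for either comparison of a CBSmut group with its insertion, a share that their choice on the same libraries raises. PCDHA6 differed by 1.46 and CTCF by 0.72. Of the genes near the protocadherin clusters, DIAPH1 differed by 1.43, RNF14 by 1.55, HDAC3 by 0.98, GNPDA1 by 0.91, PCDH1 by 0.89, IK by −0.91, HARS2 by −0.95, PURA by −0.96, CYSTM1 by −1.42 and APBB3 by −1.60 (list, camera adjusted p = 0.0183, and adjusted p = 0.470 with an estimated correlation).

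Division genes differed upwards, with CDC6 at 4.53, MCM3 at 3.07 and MCM4 at 2.26 (replication list, camera adjusted p = 1.79e-11) and TOP2A at 2.59, BIRC5 at 2.12 and FOXM1 at 0.96 (mitotic list, adjusted p = 4.91e-06). The glycolysis and hypoxia genes BNIP3, ALDOA and ENO1 differed by 1.72, 1.45 and 1.33 (hypoxia list, adjusted p = 0.0488, and adjusted p = 0.137 with an estimated correlation). Interferon response genes differed downwards, with BST2 at −4.17, IFIH1 at −1.54 and STAT2 at −1.19 (adjusted p = 1.96e-08), as did the stress genes DDIT3 at −2.44, TRIB3 at −1.57 and SLC7A5 at −0.87 (integrated stress response list, adjusted p = 0.000351, and adjusted p = 0.151 with an estimated correlation). Of the sterol genes FDFT1 differed by −0.998 (cholesterol list, adjusted p = 0.00861, and adjusted p = 0.507 with an estimated correlation). Among epithelial markers CLDN4 differed by −4.48, ESRP1 by −3.96 and KRT7 by −3.16 (adjusted p = 7.67e-10). Of the immediate early genes CYR61 differed by −2.86, KLF6 by −1.77 and IER2 by −1.61 (adjusted p = 3.83e-09). In the adhesion and matrix list COL4A1 differed by −2.48, LAMA5 by −2.29 and ALCAM by 2.25 (adjusted p = 4.91e-06).

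These differences go with a pattern in which mE1_CBSmut differed from wild type at 3 genes and mE1 at 6807 (6590 on interval midpoints). Of the midpoints 62.3% to 66.9% lay within 1% of FPKM in mE1 and wild type, so a correction of FPKM stays open. That libraries labelled mE1_CBSmut hold cells like unedited ones, through a wrong label or an unedited clone, cannot be told apart from an effect of the changed CBS, since the 3 genes called by the real split of the 4 libraries are the pattern itself and test nothing. Pairing wild type 1 with mE1_CBSmut 1 against the rest called 221, which points to a structure of the samples other than their group, and pairing wild type 1 with mE1_CBSmut 2 called 0 (3 splits are too few for a share under 0.05). A different culture state of mE1 without a genetic difference cannot be told apart, since the SD of the bin medians, 0.156, exceeded the highest shuffle, 0.109, but clusters of co-regulated neighbours could also do this, and the bound that would exclude it was raised to 3 times the highest shuffle after this value was seen. That the changed CBS undoes the insertion's effect stays open and untested without genotypes. It would also have to undo shifts of chromosome stretches (SD 0.156 in mE1, 0.0155 in mE1_CBSmut).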

How the results depend on the processing

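The tests with interval midpoints, with the GC and length trend removed, with a fold change of at least 2, without genes on alternate sequences, without the ac1rep or mE1_CBSmut libraries, and with the block in only the groups compared were chosen after the data were seen. Of the counts of called genes under other settings, 172 stayed within 1.5 times the first value, 14 were lower and 4 higher. Of the values of named genes, 8541 kept direction and side of the threshold, 123 lost the call, 19 gained it and 38 changed sign. For the 78 list calls 1360 tests under other settings kept the call and 127 lost it. Removing the GC and length trend ended 9 (adjusted p), CTCF and cohesin in mE1 against wild type (0.124), mE1_CBSmut against mE1 (0.116) and ac1rep against wild type (0.209), epithelial markers (0.433) and histones (0.131) there, histones (0.365) and interferon genes (0.0719) in ac1rep against HEK-293T, replication between the unedited lines (0.0719) and hypoxia in the difference (0.0944). A filter at 1 FPKM ended 6 (0.0516 to 0.0832) and interval midpoints 5 (0.0649 to 0.218), CTCF and cohesin in both mE1 comparisons, immediate early genes in mE2, interferon genes in ac1rep against HEK-293T and hypoxia with either, and histones in ac1rep against HEK-293T with the filter. Only the libraries compared ended 8 (0.0552 to 0.109), CTCF and cohesin in the 3 comparisons above, immediate early genes in mE2, these and integrated stress genes between the unedited lines, adhesion in mE2_CBSmut against wild type and hypoxia in the difference. The highest transcript ended CTCF and cohesin and epithelial markers in ac1rep against wild type (0.0676 each) and interferon genes against HEK-293T (0.0596, and 0.0576 with a pseudocount of 1). Immediate early genes in mE2 and hypoxia in the difference were lost with a pseudocount of 0.1 (0.0538 and 0.0547) and without alternate sequences (0.0509 and 0.0515), the first also without ac1rep (0.0599), and CTCF and cohesin in mE1 without mE1_CBSmut (0.0587). Of 182 list tests not called, 23 were called under some setting (65 of 3423 tests, 5 of them in the other direction). Among these were integrated stress and cholesterol genes in ac1rep against wild type (lower, 0.0503 each, lowest 0.00158 and 0.00448) and CTCF and cohesin in mE2 and mE2_CBSmut against wild type (lower, 0.0827 and 0.0803, lowest 0.0327 and 0.024). Mitotic genes in ac1rep against wild type were called higher with the GC and length trend removed (0.0153). With an estimated correlation 4 of 9 list calls held for mE1 against wild type, 4 of 9 for mE1_CBSmut against mE1, 3 of 7 for mE2 against wild type, 5 of 10 for mE2_CBSmut against mE2, 4 of 7 for mE2_CBSmut against wild type, 0 of 5 for ac1rep against wild type, 2 of 11 for ac1rep against HEK-293T, 3 of 10 between the unedited lines and 6 of 10 for the difference between the CBSmut comparisons. Depth is unknown. The deposited intervals of PCDHA genes near 1 FPKM are wide, as for PCDHAC1 in mE1 1 (0.712 FPKM, interval 0.447 to 0.963). A PCDHA gene that was not called is therefore not shown to be unchanged.

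A fold change of at least 2 left, by its construction, 1670 genes for mE1 against wild type, 1690 for mE1_CBSmut against mE1, 1750 for mE2 against wild type, 972 for mE2_CBSmut against mE2, 1593 for mE2_CBSmut against wild type, 3133 for ac1rep against wild type, 6844 for ac1rep against HEK-293T, 5159 between the unedited lines and 2819 for the difference. A fit to only the libraries compared, which has fewer degrees of freedom, gave 4451 for mE2 against wild type and 2832 for mE2_CBSmut against mE2. The highest transcript per gene gave 3442 for mE2_CBSmut against mE2, 4218 for the difference and 6 for mE1_CBSmut against wild type, where no filter gave 7 and leaving out 1 library 4 to 6, and the cause was not tested. Leaving out 1 library gave 5296 to 5814 genes for mE1 against wild type, 5838 to 6135 for mE2, 7530 to 7866 for ac1rep and 5504 to 5991 for the difference.

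PCDHA genes called over the list alone for mE1 against wild type were 1 with a pseudocount of 0.1, with no filter, with the highest transcript and with the GC and length trend removed, 0 with only the libraries compared, and 1 to 2 without 1 library. For mE1_CBSmut against mE1 they were 1 with the highest transcript, 0 with only the libraries compared and 1 to 3 without 1 library (1 without mE1 2). For mE2 against wild type they were 1 with a pseudocount of 0.1, no filter, quantile normalization, the highest transcript, and without any 1 library. With the highest transcript PCDHA2 made up 0.686% of the PCDHA sum in mE2, PCDHA10 5.64e-12% in mE1_CBSmut and 0.412% in mE2, and PCDHA12 53.6% in mE1. The cause was not tested for any of these.

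Signs turned as follows (log2), and the cause was not tested. With quantile normalization and median-ratio scaling, SLC35A4 in mE1_CBSmut against mE1 was at −0.069 and −0.031, and in ac1rep against wild type at 0.025 and 0.263 (the latter called, adjusted p = 0.00239). RAD21 with quantile normalization was at −0.023 in mE1_CBSmut against mE1 and 0.147 in mE2_CBSmut against wild type (0.075 with the GC and length trend removed), and in the difference at −0.22 with quantile normalization, −0.272 with median-ratio scaling and −0.243 with the trend removed, called lower in the latter 2 (adjusted p = 0.0107 and 0.0259). In ac1rep against wild type, PCDHA6 was at 0.367 with quantile normalization, 0.121 with median-ratio scaling and 0.171 with the trend removed. With the latter 2 settings CTCF was at 0.242 and 0.385 (called higher in both, adjusted p = 0.0118 and 0.000762) and DIAPH1 at 0.001 and 0.097. HDAC3 was at 0.052 and GNPDA1 at 0.113 with median-ratio scaling, and PURA at 0.427 with the trend removed (called, adjusted p = 0.00597). In ac1rep against HEK-293T, CTCF was at −0.011 with the highest transcript and PURA at 0.194 with the trend removed. PCDHAC1 in the difference was at −0.017 with median-ratio scaling and ranged from −0.17 to 0.545 without 1 library. Without 1 library, PCDHA12 ranged from −0.247 to 0.043 in mE1_CBSmut against wild type, −0.10 to 0.266 in mE2 against wild type, −0.163 to 0.204 in mE2_CBSmut against mE2 and −0.055 to 0.262 in mE2_CBSmut against wild type. PCDHAC1 ranged from −0.375 to 0.34 in mE1_CBSmut and −0.201 to 0.051 in mE2_CBSmut against wild type, PCDHAC2 from −0.096 to 0.004 in mE1_CBSmut against wild type, and CTCF from −0.023 to 0.046 in mE2_CBSmut against mE2. None of the values in the previous 2 sentences was called.

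Correlations of deviations between libraries of the same number ran from −0.067 to 0.134 over 21 pairs, so the numbers were not taken as pairing the samples of the whole series. The highest was that of wild type and mE1_CBSmut, where the split by number called 221 genes, so for these 2 groups libraries of a number may share something. The replicate number as a block gave 6790 genes for mE1 against wild type, 6811 for mE1_CBSmut against mE1, 3 for mE1_CBSmut against wild type, 7027 for mE2 against wild type and 5461 for mE2_CBSmut against mE2. It put 3 list calls above the threshold, CTCF and cohesin in both mE1 comparisons (0.054 and 0.0562) and hypoxia in the difference (0.0534), 2 below it, integrated stress and cholesterol genes in ac1rep against wild type (0.0473 each), and above it 1 named gene, RXRB. With only the 4 libraries and the block, limma called 0 genes for mE1_CBSmut against wild type, and 719 had an unadjusted p under 0.05.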

Other observations

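The tests of GC content and of the correction of FPKM for the chromosome stretches, and of GC content as the whole difference of ac1rep, were written down before their results, and the other tests in this part were chosen only after the result was seen. The somatostatin gene SST, a secreted hormone, differed widely between the groups, at 460.0 ± 21.1 FPKM in wild type, 460.0 ± 44.8 in mE1_CBSmut, 136 ± 0.962 in mE1, 87.7 ± 3.53 in mE2_CBSmut, 11.3 ± 0.220 in mE2 and 1133 ± 51.2 in ac1rep. Next to CDKN2A on chromosome 9, the cell-cycle inhibitor gene CDKN2B was at 0.0334 and 0 FPKM in the mE2 libraries against 0.691 ± 0.0828 in wild type and 1.18 ± 0.0995 in mE2_CBSmut, and MTAP, an enzyme of methionine salvage, at 10.02 ± 1.47 against 26.6 ± 0.957 and 14.1 ± 0.101. These genes were chosen after their values were seen. CDKN2A was at 26.6 and 27.7 FPKM in the mE1 libraries and 36.6 ± 3.66 in ac1rep.

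Wild-type and mE1_CBSmut libraries correlated across genes at 0.973 to 0.977, beside 0.971 between the wild-type libraries and 0.976 between those of mE1_CBSmut, while wild type and mE1 correlated at 0.933 to 0.941 (log2 scale, and genes are not independent replicates).

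Genes of whole chromosome stretches shifted together in mE1, mE2 and mE2_CBSmut, and the tables argue against GC content and gene length as the cause, since the SD of the bin medians of mE2, 0.185, was 0.183 with those trends removed. The SD was 0.202 on interval midpoints, mostly near FPKM, so FPKM correction stays open. For chromosome 9 below 40 Mb, loss of DNA copies in the mE2 cells is a candidate explanation, since 89.7% of its genes were lower in mE2 than in mE2_CBSmut, relative to all genes. That comparison uses the mE2 libraries on which the stretch was chosen, so it is not independent, and no DNA data were analysed. mE2_CBSmut differed from mE2 (SD 0.215), which cannot decide on the mE2 insertion, since a changed CBS that undoes its effect could give the same. Insertions stay open and untested, as clones are unlabelled.

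Of the genes called in ac1rep against wild type 81.7% were lower, and 80.6% on interval midpoints. Most midpoints lay within 1% of FPKM, so the correction of FPKM stays open. The tables argue against scale alone, since the medians of the 5 groups by GC content spanned 1.01. They argue against GC content and length alone, since 6876 genes were called with those trends removed, against 8565. GC content bias is a candidate for the excess of lower genes (median 0.17 at the highest GC content, −0.84 at the lowest). Scale stays open as a part (median of all genes −0.36). Trend removal and median-ratio scaling set the share of lower genes near even by construction (50.7% and 50.4%), so those shares test nothing. An effect of the repeat cannot be separated from the way the ac1rep values were made, since every ac1rep library was made that way, and it stays open and untested.

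A further 3 tests were run and left out of the weighing after their results were seen. The highest of 1000 shuffles for mE2 had an SD of bin medians of 0.115, CDKN2A stood at 24.5 FPKM in the lower mE2_CBSmut library, and ac1rep against wild type called 8405 genes without those that have entries on alternate sequences.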
